A study of Rattus norvegicus with 14 samples.

How the data were processed

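The islet arrays carry probes for 350 rat miRNAs and 22 control features, labelled in 1 colour, and were run on 4 control and 4 day 14 pregnant preparations. The deposited table gives an unnormalized signal intensity per miRNA with a detection flag, on a linear scale, and a second set of log2 values, normalized between arrays by the authors with the control features included, per the file headers and values. The series matrix holds the same deposited log2 values, with a largest difference of 4e-10. The scanner settings and the software behind the signals are not given in the sources used here. The INS832/13 values are log2 values deposited by the authors after robust multi-array averaging (RMA) with R 2.9.2 and the affy package, per the submitters' processing notes.

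Columns were matched to samples by the array names in the file headers and the labels, and no per-sample column was left over. The slide and the row of each islet array were read from the array names in the file headers, where a digit of 1 or 2 was taken as the row, and no label states either. For the islets each array's signals were divided by its 75th percentile over the 153 miRNAs detected on all 8 arrays and multiplied by the mean of these percentiles. Values were then floored at 0.810, the lowest scaled signal flagged as detected, and log2 transformed. The factors ran from 0.770 to 1.23. The 171 miRNAs detected on at least 4 of the 8 arrays were tested, and 155 were detected on no array. A level below the floor or not flagged as detected is only a bound. Similar miRNAs such as miR-27a and miR-27b, or miR-23a and miR-23b, can bind each other's probes, so values of such pairs are uncertain. For the cells the deposited values were tested without a filter.

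Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), pregnant minus control and anti-miR minus scrambled, without a replicate block, and called at a Benjamini-Hochberg adjusted p under 0.05. Lists of miRNAs fixed before the data were examined were tested with camera at a preset correlation of 0.01 when at least 3 members were tested, which held for 11 of 18 lists, with an estimated correlation and fry beside it. The lists cover beta-cell, erythroid, acinar, leukocyte, endothelial, stromal and liver miRNAs and miRNA families, and 1 list of control small RNAs matched nothing on the array. An arm or copy of a miRNA counts as a member. Named miRNAs follow a rule set before the data were examined: the 12 largest rises and falls past the threshold, filled by smallest p to 8 per direction, every measured arm of a fixed set of islet miRNAs, and the 2 members of smallest p in each list. The endothelial, liver, erythroid, hypoxia, acinar and miR-338 lists have fewer than 3 tested members and no camera test. Exact permutation tests of 4 against 4 arrays cannot give a p below 0.0286.

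The plan to test 1 transcript cluster per gene, 23 gene lists and the seed match of miR-338-3p in 3' UTRs needs a pairing of clusters with genes, or a genome, which is not used here. All 29214 clusters were tested instead, of which 29016 have distinct values. The gene table of rat assembly GRCr8 served only to find which miRNA genes neighbour each other, and 148 of the 171 tested miRNAs matched 1 locus in it. No array repeats another.

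The fits were tested on simulated arrays with the measured spreads, which for limma were shuffled over the miRNAs or clusters. With 40 of 171 miRNAs changed, limma recovered 59.8% of changes of 0.5 and 82% of changes of 1 log2 unit, with 2.31% false calls. For the cells, with 200 of 29214 clusters changed, it recovered 41.5% of changes of 0.3 and 93.9% of changes of 1 log2 unit, with 4.20% false calls. These rates hold for independent values and for the planted numbers of changes. The 40 planted miRNAs outnumber the 8 called on the real arrays, so the rates may not carry over to them. In 20 simulated sets camera passed an unadjusted p of 0.05 for 3.5% of unshifted lists of 7 islet miRNAs. The simulated miRNAs varied independently of each other, while the correlation estimated within lists on the arrays ran from 0.170 to 0.754, and 30 of the 35 splits of these arrays called at least 1 list, so the simulated rate does not carry over to them. Alternatives were other scalings, no scaling, the authors' values, other detection limits and floors, other variance priors, a replicate block, other set tests and leaving out each array.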

Results

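MicroRNA (miRNA) levels were measured on 1-colour arrays in pancreatic islets from control female rats (4 arrays) and from rats on day 14 of gestation (4 arrays). Messenger RNA levels were measured on a second kind of array in INS832/13 cells, an insulin-secreting rat beta-cell line, with 3 arrays under an anti-miR against miR-338 and 3 under a scrambled anti-miR. An anti-miR is an antisense oligonucleotide that binds a mature miRNA and blocks it. The labels call the arrays of a group biological replicates without naming animals or culture days, so p-values measure the spread between these arrays, whose number limits the precision. On the islet arrays the summed signal ran from 148467 to 229760, and 157 to 188 of the 350 miRNAs were detected. Arrays of a group correlated at Pearson's r of 0.946 to 0.993 across the 171 tested miRNAs of the islets and 0.998 to 0.999 across transcript clusters of the cells, and miRNAs and clusters are not independent replicates.

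The first comparison asked which islet miRNAs differ between pregnant and control rats. MiR-338, encoded in an intron of the Aatk gene, fell by 1.13 on the log2 scale (SE 0.18, n = 4 per group, limma adjusted p = 0.0204), which is 2.18-fold lower. Its normalised signal was 218 ± 49.8 (SD, n = 4) in control islets and 99.0 ± 15.6 (SD, n = 4) in islets of pregnant rats, and all 4 pregnant arrays lay below all 4 control arrays. MiR-335, encoded in the imprinted Mest gene, fell by 0.74 (SE 0.15, limma adjusted p = 0.0430), and miR-322, the rodent counterpart of miR-424, fell by 0.51 (SE 0.08, limma adjusted p = 0.0204). MiR-30a*, the minor strand of the miR-30a hairpin, fell by 0.45 (SE 0.10, limma adjusted p = 0.0430). Higher in pregnancy were miR-93 of the miR-106b/25 cluster (log2 change 0.59, SE 0.10, normalised signal 29.4 ± 1.63 in control islets and 44.3 ± 5.25 in pregnancy, SD, n = 4) and miR-27b (0.50, SE 0.09, 1.41-fold), each at a limma adjusted p of 0.0204. MiR-325-3p (0.45, SE 0.09, 1.36-fold) and miR-24 (0.34, SE 0.07, 1.27-fold) also rose, each at a limma adjusted p of 0.0430.

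**Figure D1:**
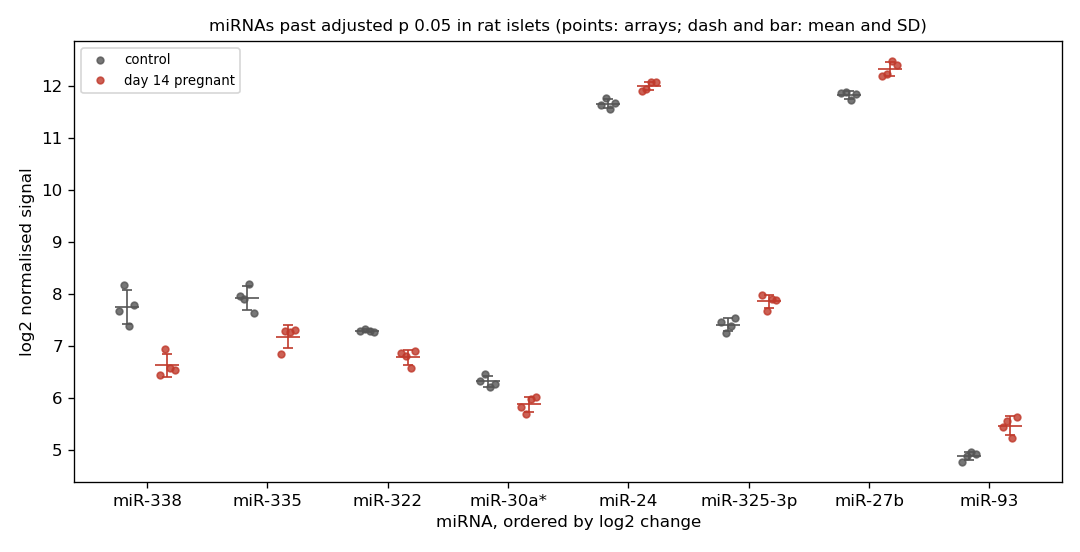
Log2 normalised signal (vertical axis) of the 8 miRNAs past an adjusted p of 0.05 (horizontal axis), with each array as a point and mean and SD as dash and bar for 4 control and 4 pregnant preparations. The groups were fully separate for all 8, and miR-338 averaged 7.74 in control islets against 6.62 in pregnancy.

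Of the 171 miRNAs tested, 4 rose and 4 fell, and 42 had an unadjusted p under 0.05. The groups did not overlap for 25 miRNAs, 14.6% of those tested, where chance gives 2.86%. The split of calls moved with the scaling: quantile normalization gave 3 higher and 7 lower, and the authors' processed values 1 higher and 5 lower. Scaling to the percentile of all miRNAs on the array moved every log2 change up by 0.15, the median from -0.02 to 0.13 and miR-30a* to -0.29, and left 1 higher and 1 lower. By the array names in the file headers, which no label explains, all 8 arrays shared a slide with 2 rows. With the row as a block, a fit chosen after the data were seen, the calls came to 23 (4 higher, 19 lower). Within row 1 (3 pregnant, 1 control) miR-338 differed by -1.48 and within row 2 (1 pregnant, 3 control) by -1.17, against -1.32 with the row as a block. The groups of all 8 called miRNAs did not overlap, so their direction within a row was fixed in advance and only the size could vary. Within rows 1 and 2 miR-335 differed by -0.61 and -1.08, miR-322 by -0.57 and -0.42 and miR-30a* by -0.57 and -0.45. MiR-93 differed by 0.59 and 0.57 and miR-27b by 0.50 and 0.37. MiR-325-3p differed by 0.57 and 0.51 and miR-24 by 0.26 and 0.29. Leaving out 1 array left 0 calls without control replicate 1, 2 or 4 or pregnant replicate 1 or 4, 1 call without control replicate 3, 2 without pregnant replicate 3 and 19 without pregnant replicate 2, while the log2 change of miR-338 stayed between -1.25 and -0.99.

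Other named miRNAs did not pass the threshold. MiR-144 and miR-451, which share a locus and are abundant in erythroid cells, had log2 changes of 1.70 (SE 0.47, limma adjusted p = 0.0852) and 1.14 (SE 0.38, limma adjusted p = 0.123). MiR-182 had a log2 change of 0.69 (SE 0.18, limma adjusted p = 0.0717) and miR-384-3p one of 0.80 (SE 0.26, limma adjusted p = 0.123). On the lower side, miR-100 had a mean normalised signal of 54.4 in control islets and 27.3 in pregnancy (limma adjusted p = 0.0852), miR-30c-2* a log2 change of -0.61 (SE 0.14, limma adjusted p = 0.0568), miR-125b-5p one of -0.38 (SE 0.10) and miR-30a one of -0.35 (SE 0.09), the last pair at a limma adjusted p of 0.0717. MiR-384-3p was detected on 2 of 4 control arrays and miR-30c-2* on 1 of 4 pregnant arrays, so both of these log2 changes rest in part on signals that are only bounds. MiR-182, at a mean normalised signal of 15.6 in control islets and 24.9 in pregnancy, lay near the level of the negative control features. Under scaling to all miRNAs on the array miR-125b-5p stood at -0.23 and miR-30a at -0.20, and with the stromal mean as a covariate miR-100 stood at -0.51 and miR-30c-2* at -0.40.

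Among the 10 tested miRNAs of the beta-cell and neuroendocrine list, 1 fell (miR-335) and 9 did not pass, and the count adjusted over the list alone was also 1. MiR-375, the most studied islet miRNA, had a log2 change of -0.06 (SE 0.11, limma adjusted p = 0.761), and miR-7a one of -0.10 (SE 0.10, limma adjusted p = 0.592). Under scaling to all miRNAs on the array these turned to 0.09 and 0.05, and miR-375 also to 0.016 without control replicate 3, 0.015 without pregnant replicate 2 and 0.04 with the slide row as a block. With the stromal mean as a covariate miR-375 stood at -0.20 and miR-7a at -0.22, and miR-7a at 0 with quantile normalization or the authors' processed values and at -0.02 without pregnant replicate 2. MiR-7b had a log2 change of -0.36 (SE 0.11, limma adjusted p = 0.121), miR-7a* one of 0.13 (SE 0.11), and miR-132 one of -0.30 (SE 0.20). Scaling to all miRNAs on the array gave -0.21, 0.28 and -0.15 for these, and without 1 array miR-7a* ran from 0.05 (control replicate 2) to 0.20 (control replicate 4) and miR-132 from -0.46 (control replicate 4) to -0.19 (pregnant replicate 2). Neither miR-184 nor miR-338*, the minor strand of the miR-338 hairpin, was detected on enough arrays to be tested. The camera test gave the list an adjusted p of 0.377 (adjusted p = 0.808 with an estimated correlation). With the stromal mean as a covariate it was called lower (adjusted p = 0.0273, median log2 change -0.21 against -0.08), and the median turned to 0.07 under scaling to all miRNAs on the array. The median was -0.13 without pregnant replicate 1, -0.0082 without pregnant replicate 2 and -0.00091 without the detection filter.

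In the miR-30 family 1 of 8 tested members fell (miR-30a*) and 7 did not pass, against 4 past the threshold when adjusted over the list alone, among them miR-30c-2* with its 1 detected pregnant array. Its camera adjusted p was 0.129 (adjusted p = 0.631 with an estimated correlation), and its median log2 change of -0.13 became 0.02 under scaling to all miRNAs on the array. In the miR-17/92 and paralogous clusters 1 of 7 tested members rose (miR-93), as many as when adjusted over the list alone, and all 7 had a positive log2 change, miR-106b at 0.27 (SE 0.11, limma adjusted p = 0.149) or 0.42 under scaling to all miRNAs on the array. The camera adjusted p of these clusters was 0.0521 (adjusted p = 0.631 with an estimated correlation). Over the other fits it ran from 1.02e-05 with the stromal mean as a covariate to 0.387 without pregnant replicate 2, where the median log2 change of 0.24 turned to -0.0032. The median was 0.66 with the stromal mean as a covariate and 0.39 under scaling to all miRNAs on the array. With the slide row as a block the median was 0.08 (adjusted p = 0.229) and without control replicate 1 the adjusted p was 0.176. It passed without control replicate 2 (0.0163) and without pregnant replicate 1 (0.0256) or 3 (0.00633). It also passed with the authors' processed values (0.0155), quantile normalization (0.0230), no scaling (0.0278), the replicate block (0.0344) and no detection filter (0.0437). No member of the cluster that holds miR-182 and miR-96 passed over all miRNAs tested and 1 of 3 passed when adjusted over the list alone (miR-182), with miR-96 at 0.18 (SE 0.11), from 0.05 with the stromal mean as a covariate to 0.35 with quantile normalization. The camera adjusted p of that cluster was 0.129 (adjusted p = 0.631 with an estimated correlation). Without pregnant replicate 2 it was 0.0337, with a median of 0.27 against 0.18.

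The miRNAs of the imprinted Dlk1-Dio3 locus were the only list that the camera test called. Its adjusted p was 0.000625 (adjusted p = 0.631 with an estimated correlation), and 24 of 25 tested members had a positive log2 change, with a median of 0.13. The median was 0.05 without control replicate 2 and 0.08 without pregnant replicate 4, 0.23 without control replicate 1 and 0.22 without pregnant replicate 2. It was 0.06 with the stromal mean as a covariate, 0.21 with the slide row as a block, and 0.28, 0.25 and 0.24 under scaling to all miRNAs, quantile normalization and the authors' processed values. No member passed by itself, either over all miRNAs or adjusted over the list alone. Tested across arrays, the mean of the list differed by 0.195 (SE 0.125, exact permutation p = 0.171, adjusted over the list scores 0.324) and did not pass. Control replicate 1 (6.46) lay above pregnant replicates 1, 2 and 3 (6.33, 6.27 and 6.40) and below pregnant replicate 4 (6.53). Control replicates 2, 3 and 4 (5.93, 6.13 and 6.22) lay below all pregnant arrays. MiR-411 had a log2 change of 0.43 (SE 0.15) and miR-376b-5p one of 0.42 (SE 0.15), each at a limma adjusted p of 0.123, and miR-411 stood at 0.26 with the stromal mean as a covariate. With the mean of the stromal miRNAs as a covariate, a fit chosen after the data were seen, the adjusted p was 0.193, and the mean of the list was 0.47 higher within slide row 1 and 0.06 higher within row 2, against 0.26 (SE 0.15) with the row as a block.

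Markers of other cell types differed between arrays. All 6 tested stromal and smooth muscle miRNAs had negative log2 changes, with 0 past the threshold over all miRNAs and 1 when adjusted over the list alone, miR-10b at -1.04 (SE 0.29, limma adjusted p = 0.0883). MiR-143 differed by -1.42 (SE 0.53, limma adjusted p = 0.142), and its log2 signal in control replicate 2 was 12.60 where the other control arrays read 9.96 to 10.65. Without that array miR-143 differed by -0.87. The camera adjusted p of the stromal list was 0.129 (adjusted p = 0.720 with an estimated correlation). The camera call is reached under scaling to all miRNAs on the array (adjusted p = 0.0369), without scaling (0.0278), with the replicate block (0.0422), without the detection filter (0.0436) and without pregnant replicate 2 (0.0299). Both tested erythroid miRNAs, miR-144 and miR-451, passed when adjusted over the list alone. The 7 tested leukocyte miRNAs gave 0 calls, also over the list alone, with miR-342-3p at -0.16 (SE 0.12), miR-146b at 0.07 (SE 0.09) and a camera adjusted p of 0.583 (adjusted p = 0.808 with an estimated correlation). Their median of 0.14 turned to -0.30 without pregnant replicate 2 and to -0.10 with the slide row as a block. It was 0.35 and 0.34 without pregnant replicates 1 and 3, 0.29 under scaling to all miRNAs and 0.06 without control replicate 3. The list was called higher with the stromal mean as a covariate (adjusted p = 0.0175, median 0.81). MiR-342-3p stood at -0.28 without pregnant replicate 2, -0.10 without pregnant replicate 4, -0.014 under scaling to all miRNAs and -0.02 with the stromal mean as a covariate. MiR-146b stood at 0.14 and 0.02 without pregnant replicates 1 and 4, 0.04 without control replicate 3, 0.22 under scaling to all miRNAs and 0.02 with the slide row as a block. MiR-216a, the 1 tested acinar miRNA, had a log2 signal of 4.73 and 4.69 in pregnant replicates 1 and 3 and of 7.92 and 7.59 in replicates 2 and 4, against 6.83 to 8.29 in control islets, and a log2 change of -1.12 (SE 0.83, limma adjusted p = 0.445), which turned to 0.22 with the stromal mean as a covariate. It stood at -0.62, -1.68 and -0.60 without pregnant replicates 1, 2 and 3 and at -1.93 with the slide row as a block. The endothelial miR-126 had a log2 change of -0.26 (SE 0.10, limma adjusted p = 0.142), which came to -0.11 under scaling to all miRNAs, quantile normalization and the authors' processed values and to -0.13 with the stromal mean as a covariate. MiR-126*, detected on 3 of 4 pregnant arrays, had one of -0.03 (SE 0.16), which turned to 0.12 under scaling to all miRNAs on the array, 0.16 with quantile normalization, 0.10 with the authors' processed values, 0.19 with the stromal mean as a covariate, 0.03 without control replicate 1 and 0.10 without pregnant replicate 3, and was -0.15 without pregnant replicate 2 and -0.13 without control replicate 3.

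**Figure D2:**
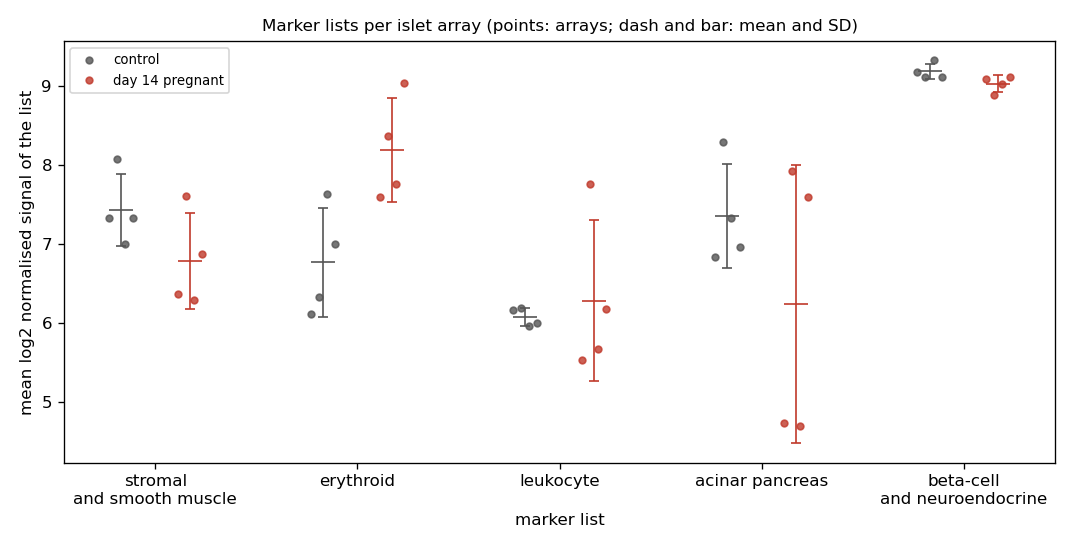
Mean log2 normalised signal (vertical axis) of 5 marker lists (horizontal axis) on each islet array, with mean and SD as dash and bar for 4 control and 4 pregnant preparations. Stromal means were 7.43 in control islets and 6.78 in pregnancy, erythroid means 6.76 and 8.19, and the leukocyte list stood at 7.75 in 1 pregnant array where the others read 5.52 to 6.17.

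In the remaining lists 0 members passed over all miRNAs. The miR-200 family, with miR-200b at -0.29 (SE 0.13) and miR-141 at 0.12 (SE 0.07), had a camera adjusted p of 0.690 (adjusted p = 0.808 with an estimated correlation). The let-7 and miR-98 family, with let-7i at -0.21 (SE 0.06, limma adjusted p = 0.0852) and let-7d at -0.09 (SE 0.06), had one of 0.583 (adjusted p = 0.808 with an estimated correlation). For the miR-29 family, with miR-29a at -0.18 (SE 0.06, limma adjusted p = 0.123) and miR-29b at -0.14 (SE 0.06), it was 0.129 (adjusted p = 0.631 with an estimated correlation). This family was called lower with the stromal mean as a covariate (adjusted p = 0.0175, median -0.21). The miR-200 median was -0.07 without pregnant replicate 2, -0.08 without control replicate 2 and -0.17 without control replicate 1. The let-7 median was -0.02 without control replicate 2 and -0.06 without control replicate 1. The family medians of -0.12, -0.04 and -0.13 turned to 0.03, 0.11 and 0.02 under scaling to all miRNAs on the array, as did let-7d (0.06) and miR-29b (0.0093). In that scaling miR-29a came to -0.025, let-7i to -0.06 and miR-200b to -0.14, and miR-141 came to 0.28. Quantile normalization gave 0 for miR-29a, -0.08 each for let-7i and miR-29b, -0.04 for let-7d and -0.09 for miR-200b, and the authors' processed values 0.03 for miR-141. The cell-cycle list, with miR-195 at -0.65 (SE 0.20) and miR-497 at -0.63 (SE 0.23), had a camera adjusted p of 0.583 (adjusted p = 0.808 with an estimated correlation). With the stromal mean as a covariate these came to -0.29 and -0.21. Adjusted over the list alone, 0 members of these 4 lists passed. The mixed test of fry, which asks for change in either direction and compares a list with no other, gave adjusted p-values of 0.00516 for the miR-30 family and 0.0161 each for the let-7 family and the beta-cell list, while no list passed its directional test. Of the 2 tested liver miRNAs 1 passed when adjusted over the list alone, miR-192 at -0.48 (SE 0.15, limma adjusted p = 0.112), with miR-194 at -0.39 (SE 0.20). These came to -0.32 and -0.20 with quantile normalization. The hypoxia and p53 miRNAs miR-34a (-0.28, SE 0.33) and miR-210 (-0.01, SE 0.11) passed neither way. MiR-34a turned to 0.0044 without control replicate 2, whose log2 signal was 8.31 where the other control arrays read 7.03 to 7.28, and to 0.25 with the stromal mean as a covariate. It stood at -0.42 without control replicate 1, -0.095 and -0.46 without pregnant replicates 1 and 2, -0.13 under scaling to all miRNAs and -0.75 with the slide row as a block. MiR-210 turned positive, to at most 0.15, under scaling to all miRNAs on the array, with quantile normalization, the authors' processed values and the stromal mean as a covariate. It did so too without control replicate 1 (0.04) or 2 (0.0076) or pregnant replicate 1 (0.03) or 3 (0.06).

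The second comparison asked which transcripts of INS832/13 cells differ when miR-338 is blocked. Of 29214 transcript clusters 251 passed the limma test, 31 higher and 220 lower under the anti-miR, and 4364 had an unadjusted p under 0.05. A set of 31 clusters stood apart from all others, with log2 changes from -2.46 to -1.66 and a median of -1.95, which is 3.87-fold lower. The largest fall was that of transcript cluster 10722381, by 2.46 on the log2 scale (SE 0.14, limma adjusted p = 0.00187), from a log2 value of 8.26 ± 0.20 (SD, n = 3) under the scrambled anti-miR to 5.80 ± 0.21 (SD, n = 3). Cluster 10722407 fell by 2.26 (SE 0.13, limma adjusted p = 0.00195). Among the called clusters the largest rises were those of 10866140 (0.74, SE 0.11, limma adjusted p = 0.0472) and 10909849 (0.48, SE 0.06, limma adjusted p = 0.0374). Cluster 10866140 was dim, at a log2 value of 3.93 ± 0.22 (SD, n = 3) under the scrambled anti-miR and 4.67 ± 0.03 (SD, n = 3) under the anti-miR. The array medians were 7.81 to 7.84. The files do not pair cluster identifiers with genes, so no cluster is named by gene here, and the level of miR-338 under the anti-miR is not measured in these values.

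**Figure D3:**
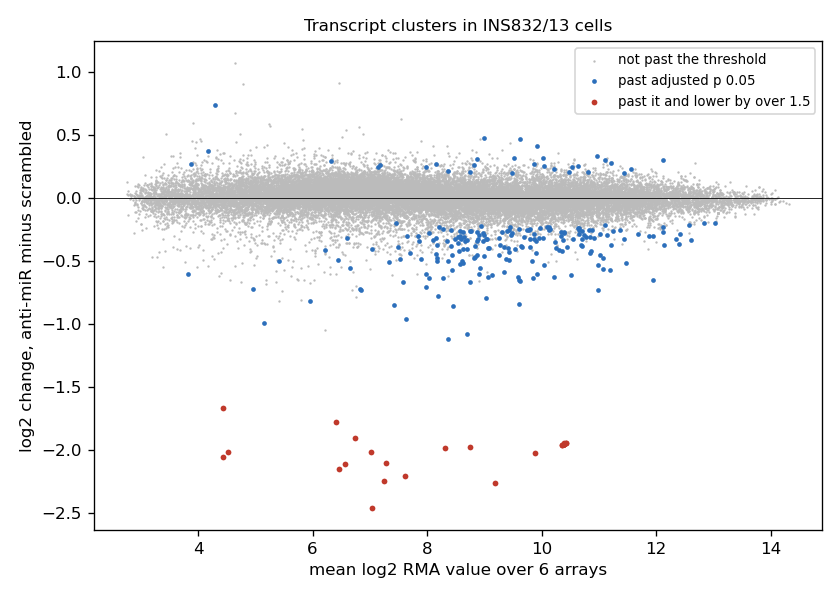
Log2 change between anti-miR and scrambled control (vertical axis) against the mean log2 RMA value over 6 arrays (horizontal axis), 1 point per transcript cluster. The 31 clusters lower by over 1.5 log2 units lie apart, and the largest change among the other called clusters is 1.12 in size.

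Outside this set 220 clusters were called, 31 higher and 189 lower, with a median absolute log2 change of 0.34. The set of 31 holds 20 distinct value profiles, since clusters with identical values on all 6 arrays occur in it, and counting identical profiles once gave 230 calls (26 higher, 204 lower). Leaving out any array gave 54 to 73 calls: 55, 58 and 73 without anti-miR replicates 1, 2 and 3, and 68, 54 and 57 without scrambled replicates 1, 2 and 3. The clusters at or above the median level gave 910 calls, and both named rises lost their call without anti-miR replicate 1, 2 or 3 or scrambled replicate 2 or 3.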

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

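The weighing of the stromal and erythroid pattern and of the set of transcript clusters rests on tests chosen after their results were seen, and those of miR-338 were set before their values were seen, on fits added after the data were examined. Of 122 groups of 4 values 8 had an array far from the rest, where chance gives about 5%. In pregnant islets these were replicate 1 for miR-335 (log2 signal 6.84, others 7.26 to 7.30), replicate 4 for miR-29a (12.59, others 12.52 to 12.53) and replicate 2 for the mean of the miR-29 family (11.18, others 11.35 to 11.36). In control islets they were replicate 1 for miR-182 (4.39, others 3.75 to 3.84) and miR-106b (7.71, others up to 8.04), replicate 3 for miR-126 (10.67, others 10.75) and miR-7b (10.41, others 10.04 to 10.07), and replicate 2 for the hypoxia and p53 list (7.76, others 7.12 to 7.22).

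Among miRNAs detected on too few arrays to be tested, 5 had a detected signal over 3 times the highest control array. MiR-142-5p, a leukocyte miRNA, had a normalised signal of 312 in pregnant replicate 2 against at most 4.81 in control islets, and miR-17-5p in the same array 23.7 against 4.46. In pregnant replicate 4 these were miR-130b (17.5 against 4.35), miR-32 (7.67 against 2.28) and miR-374 (4.54 against 1.30). This rule did not look for signals higher in control islets. Detected in control islets alone were miR-1, miR-145 and miR-205 on 1 array each, miR-139-5p and miR-133b on 2 and miR-218 on 3. Of these miR-1, miR-145 and miR-133b belong to the stromal list, and none was tested.

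MiR-338 was lower in islets of pregnant rats. With the slide row, as read from the array names, as a block its log2 change was -1.32 (SE 0.16, limma adjusted p = 0.0149). Its groups did not overlap, so the direction within a row was fixed in advance and only the size could vary. That size argues against the position on the slide as the whole cause, with 1 array of a group in each row. With the mean of the stromal miRNAs as a covariate the log2 change of miR-338 was -0.84 (SE 0.12, limma adjusted p = 0.0387). That mean is an imprecise measure of stromal content. A remainder could stay even if content were the whole cause, so the fit does not decide this. Control replicate 2 had the highest control values of miR-338 (8.16) and the stromal mean (8.07), and control replicate 3 the lowest (7.38 and 6.99). Pregnant replicate 2 had a stromal mean of 7.61 with miR-338 at 6.93. Lower stromal content as the cause stays open. So does a difference between pregnant and control islet cells, or in other cell types the lists miss, which was not tested further.

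Stromal miRNAs had negative log2 changes and erythroid miRNAs positive ones in islets of pregnant rats, and neither score passed (exact permutation p = 0.171 and 0.0571, where 0.0286 is the smallest possible; adjusted over 17 lists, 0.324 and 0.139, which this design leaves little room to pass). A higher share of endocrine cells would lower both alike. The erythroid score was instead higher by 1.42 (SE 0.48). The beta-cell score was not higher, at -0.15 (SE 0.07, exact permutation p = 0.0571). The median of that list turned to 0.07 under scaling to all miRNAs on the array. The erythroid minus stromal score differed by 2.07 (SE 0.60), with an exact permutation p of 0.114 corrected over the 15 pairs of 6 marker lists. None of these scores passed, so a higher endocrine share stays open. More whole blood would raise leukocyte miRNAs, and their score differed by 0.20 (SE 0.51, exact permutation p = 0.914), but that value rests on pregnant replicate 2 (7.75, other pregnant arrays 5.52 to 6.17, control arrays 5.96 to 6.18, list median -0.30 without it, and 0.81 with a camera adjusted p of 0.0175 with the stromal mean as a covariate), so whole blood stays open. Without control replicate 2 the stromal score differed by -0.43 (SE 0.32, exact permutation p = 0.314), but the camera adjusted p of the list was 0.0299 without pregnant replicate 2 (0.0278 to 0.313 over the other scalings, filters, blocks and arrays left out) and its mean differed by -1.15 within slide row 1, which holds control replicate 2, and by -0.85 within row 2, which does not and has 1 pregnant array. Whether 1 control array accounts for the stromal part stays open, as does pregnancy itself for both parts.

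A set of transcript clusters was about 3.87-fold lower under the anti-miR. The deviations of its distinct profiles from the group means correlated at a median of 0.71, so its clusters are not independent measurements. That correlation cannot tell near-identical copies read by shared probes from separate transcripts that vary together. In the set 10 clusters had identical values on all arrays, so these are not separate measurements. Its identifiers lie in runs: 4 of the 4 clusters from 10707641 to 10707647, and 27 of the 28 on the array from 10722365 to 10722419. The other sets of 4 or more clusters with identical values changed by at most 0.12 in size (log2 change -0.12, SE 0.10), which argues against a loss of every multi-copy set. An effect of the anti-miR stays open.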

How the results depend on the processing

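The fits with the slide row and the stromal mean in islets, and those with identical clusters counted once or the lowest clusters left out, were chosen after seeing the data. The miRNA calls in islets (8) came to 2 under the percentile of all miRNAs, 0 without scaling (20 at an unadjusted p under 0.05), 0 without the detection filter (48 at an unadjusted p under 0.05), 23 with the slide row as a block and 1 with the stromal mean as a covariate. Leaving out 1 array gave 0 to 19, and the cause was not tested. The 8 were all among the calls under the higher floor and with detection on all 8 arrays, and 4, 2, 7 and 4 of them under quantile normalization (10 calls), the authors' values (6), trend and robust priors (11) and the replicate block (10). The higher floor and the stricter detection limit leave the values of the 8 unchanged, so their result was nearly fixed in advance. Of 831 values of named miRNAs under alternatives 98 lost a call, 33 gained one, 0 reversed with a call and 27 changed sign without one. Only the 8 called miRNAs could lose a call, so the 98 are not to be read against all 831. They are most of the values of those 8.

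The list calls (1) came to 2 under the percentile of all miRNAs, quantile normalization and the authors' values, 3 without scaling and without the detection filter, 3 with the replicate block, 4 with the stromal mean as a covariate, 0 with an estimated correlation and 0 with fry (2 at an unadjusted p under 0.05), and from 1 to 3 without 1 array; the cause was not tested.

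The cluster calls (251) came to 910 among clusters at or above the median level, where fewer were tested, 588 with trend and robust priors, 54 with the replicate block and 54 to 73 without 1 array. They came to 306, 370, 230 and 177 under quantile normalization again, median centring, identical clusters counted once and the lowest clusters left out. Replicate numbers showed no pairing in islets, where deviations of same-numbered arrays correlated at -0.14, 0.17, -0.28 and -0.49. In cells these correlations were weak, at 0.05, 0.09 and 0.03, but each cell array correlated best with its own number. Whether the numbers pair the cell arrays is therefore not settled. The gene lists and the seed match were not run, and the test of 1 cluster per gene was not run. Signal near background limits what 155 undetected miRNAs can show. It also limits dim miRNAs that were tested, such as miR-93, miR-182, miR-384-3p, miR-411, miR-376b-5p and miR-30c-2*. Their mean signals lay near those of the negative control features.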

Other observations

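The tests of other splits and of neighbouring genes were set before their results were seen, and that of the paralogous pairs after. MiR-218 was detected on 3 of 4 control arrays and on 0 pregnant arrays, and miR-133b, a muscle miRNA, on 2 control arrays and 0 pregnant arrays. No fold is given, since a signal not detected is only a bound, and neither was tested.

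MiR-27b and miR-23b lie in 1 cluster and miR-27a and miR-23a in another. The log2 changes were 0.50 and 0.32 for the first pair and -0.26 and -0.31 for the second. The difference between the pair means differed by 0.69 between the groups (SE 0.16, exact permutation p = 0.0286, the smallest possible). The pairs were chosen after their changes were seen, so this p decides nothing about a difference between the clusters.

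Neighbouring miRNA genes within 10 kb changed alike. Their log2 changes differed by 0.26 on average over 101 pairs, against 0.49 under random reassignment (permutation p = 0.00080 over 10000 reassignments). Shared primary transcripts may account for this, but the 25 pairs with no member in the Dlk1-Dio3 list gave 0.32 against 0.49 (permutation p = 0.0584), and whether it holds outside that locus stays open.

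Of the 35 splits of the 8 islet arrays into groups of 4, 1 gave as many miRNA calls, the real one with 8. The highest of the others gave 1. That share is under 0.05, which argues against chance for the count in the main fit. It is also the lowest share that 35 splits can give, and the count moved with the processing and the arrays used, so chance is not excluded. The split by slide row gave 0 calls. For the lists 30 of the 35 splits gave as many as the real 1, and the highest of the others gave 5, so chance cannot be excluded for the Dlk1-Dio3 call; the split by slide row gave 4. For the 6 arrays of the cells there are 10 splits, too few for a share under 0.05: 1 gave as many cluster calls, the real one with 251, and the highest of the others gave 0.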
